A study of Mus musculus with 6 samples.

How the data were processed

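Bulk RNA-seq of the anterior cingulate cortex was deposited for 6 mouse libraries, 3 labelled WT and 3 labelled KO for Ythdf1. Per the labels' protocols, RNA was taken up in Trizol, polyadenylated RNA was selected on oligo(dT) beads, and strand-marking libraries made with dUTP were sequenced in pairs on an Illumina NovaSeq. Per the submitters' processing notes the tools were cutadapt 1.9, HISAT2 2.2.1 and StringTie 2.1.6, with DESeq2 and edgeR named without a version. The genome build, the counting method and its strand setting are not given in the sources used here.

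The authors deposited a table of whole-number counts per gene for 55401 genes, with no normalization, and the gene counts were used as deposited. The authors also deposited a table of transcripts they listed as differing, with an FPKM value per library (fragments scaled by transcript length and library size, by the authors), a log2 ratio of the group means, p-values and q-values. In the deposited table the direction written beside each of the 537 transcripts was that of its mean FPKM in the libraries labelled KO against those labelled WT, while the sheet named for higher transcripts held the 287 lower ones and the sheet named for lower transcripts the 250 higher ones. The directions written beside the transcripts were used. The deposited ratios of transcripts with a group at 0 are not printed. Of the gene identifiers, 55141 had a symbol and a place in GENCODE M21 (GRCm38), and 530 of the 537 listed transcripts were found there, all 530 with the same start, end and strand, so positions are given in GRCm38. Rows with no symbol held about 0.008% of the counts and were kept.

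The counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, scaled by TMM factors (0.993 to 1.01) and compared with the quasi-likelihood F-test at the package's default settings, libraries labelled KO against libraries labelled WT, with no covariate. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. CPM values are relative to the TMM-scaled library size, and the SE of a log2 fold change is its size divided by the square root of the F statistic. With 61792250 to 69848835 counts per library, edgeR's dispersion was above the counting variance in all 20587 tested genes, by a factor of 1.45 at the lowest and 11.9 at the median. Of 35 fixed lists, 33 were tested with camera (limma 3.58.1) on voom log2 CPM values with a preset correlation between genes of 0.01, adjusted over the 33 lists, then with an estimated correlation and with fry, which asks whether a list's own genes move on balance 1 way. Both remaining lists, the Y-linked genes and Xist, were read only as levels. Medians of lists carry a bootstrap interval from 1000 draws over genes.

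The lists, the test, the alternatives and the rule for named genes were fixed before the data were examined. Named were Ythdf1 and Cap1, then genes past the threshold, and, with fewer than 5 past it in a direction, the 10 genes with the smallest unadjusted p in that direction with a mean of at least 1 CPM and a symbol that is not a clone, predicted-gene or pseudogene name. Up to 4 members with the smallest p were named for each list past the set test. Some genes and a list chosen in these ways are not reported here. Of the 68 genes named by that rule, 12 had another gene matching at 95% identity or more over at least 150 bases (blastn 2.17.0) and 24 had exons overlapping those of another gene, so their counts are uncertain where reads could be shared.

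Other settings chosen at the same time were DESeq2 1.42.0, limma voom, other scaling factors (RLE, upper quartile, library totals), no filter on low counts or a mean of at least 1 CPM, the replicate number as a block, other thresholds, and each library left out in turn. Chosen after seeing the data were edgeR with robust=TRUE and with legacy=FALSE, upper-quartile factors for the lists, and counts thinned to 50%. The pipeline was tested on simulated data, with 50 genes of at least 1 CPM planted at each fold size among 20034 tested. Of these, 8% at 1.2-fold, 48% at 1.5-fold, 70% at 2-fold and 100% at 4-fold were called, with 7 false calls. The simulated spread was more even than the real one (prior degrees of freedom 12.6 against 5.23), so these shares may overstate what the real comparison could find. A list planted at 1.2-fold was called by camera with the preset correlation, and so was 1 other list. Genes were simulated independently of each other, so this does not show how often lists of correlated genes pass without a change. The estimated correlation and fry were not tried on simulated data, so what they could find is not known. Overlap with the deposited transcript table used the genes tested on counts as background, since the authors' tested set is not used here. Windows of 10 Mb were compared by a hypergeometric test on genes at an unadjusted p under 0.01, then on the 12674 tested genes with no match of 95% identity over 150 bases in another gene (blastn of the longest transcript). Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.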

Results

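RNA from the anterior cingulate cortex of adult mice, a midline frontal area that takes part in mood and pain, was sequenced in 6 bulk libraries, 3 labelled Ythdf1 wild type (WT) and 3 labelled Ythdf1 knockout (KO). YTHDF1 is a cytoplasmic reader of N6-methyladenosine (m6A) in mRNA, and the series title ties it to CAP1, a cyclase-associated protein that returns actin monomers to the filament cycle. The comparison asked which genes and gene groups differed between the genotypes. The deposited gene counts summed to 66740463, 65804611 and 66467009 in WT replicates 1, 2 and 3 and to 69848835, 61792250 and 62651918 in KO replicates 1, 2 and 3. Xist was at 8 to 24 counts and the Y-linked gene Ddx3y at 4363 to 5166 counts in the 6 libraries. The labels speak of replicates and do not say that each came from a separate animal, so the p-values measure the spread between these samples, which may be technical. Pairs of libraries differed by a chi-square per degree of freedom of 18.0 to 43.2 across genes, so no library was a copy of another. Pairs within a group lay at 18.7 to 32.0, far above counting noise alone. That argues against repeated sequencing of the same library, but not against separate preparations from the same animal. The first principal component, with 23.8% of the variance, placed WT replicates 1, 2 and 3 at -30.2, 21 and -40.4 and KO replicates 1, 2 and 3 at 14.8, 47.2 and -12.3, without parting the genotypes.

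Ythdf1 mRNA was not lower in the libraries labelled KO, Cap1 mRNA was at the same level in both groups within the spread of the replicates, and edgeR's test across all genes called 0 genes (1083 at an unadjusted p under 0.05), as limma voom did, while DESeq2 called 8 higher and 23 lower. Ribosomal protein, oxidative phosphorylation and mature oligodendrocyte genes were on the whole higher in the libraries labelled KO, with list medians of 0.18, 0.12 and 0.30 on the log2 scale. Meningeal, vascular and striatal marker genes were on the whole lower, with medians of -0.87 for meningeal, -0.33 for endothelial and -0.40 for striatal markers. Without WT replicate 1 the meningeal median was -0.56, without KO replicate 1 the oligodendrocyte median was 0.11 and the endothelial one -0.21, and without WT replicate 2 the striatal median was -0.04. These group differences passed a set test with a preset correlation between genes, and none of them passed with an estimated correlation (lowest adjusted p = 0.471 with an estimated correlation). Other splits of the 6 libraries into 3 and 3 passed up to 17 lists in that test, against 13 for the genotypes.

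Ythdf1 (ENSMUSG00000038848, chromosome 2, 180904377 to 180920949 in GRCm38) was counted in every library. It stood at 55.8, 53.3 and 49.0 CPM (counts scaled to a common library size) in WT replicates 1, 2 and 3 and at 58.2, 62.1 and 57.2 CPM in KO replicates 1, 2 and 3. The means were 52.7 ± 3.43 and 59.2 ± 2.60 CPM (SD, n = 3 each). The log2 fold change was 0.17 with a standard error (SE) of 0.066, and edgeR's quasi-likelihood test gave a Benjamini-Hochberg adjusted p of 0.93. The gene total therefore does not show the knockout that the label names, and every direction below is drawn between libraries labelled KO and libraries labelled WT. The labels do not describe the allele, and a total over the whole gene cannot show a small deletion or a frameshift, so it does not measure the protein. Cap1 (ENSMUSG00000028656, chromosome 4, 122859047 to 122886056) stood at 206.0 ± 3.74 CPM in the libraries labelled WT and 203.7 ± 6.57 CPM in those labelled KO (SD, n = 3 each). Its log2 fold change was -0.02 with an SE of 0.047 (edgeR adjusted p = 0.991), and it was 0.01 without KO replicate 2 (edgeR adjusted p = 0.998). The exons of Cap1 overlap those of Ppt1 on the opposite strand, so reads from the pair could be told apart only by a strand-aware count.

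**Figure D1:**
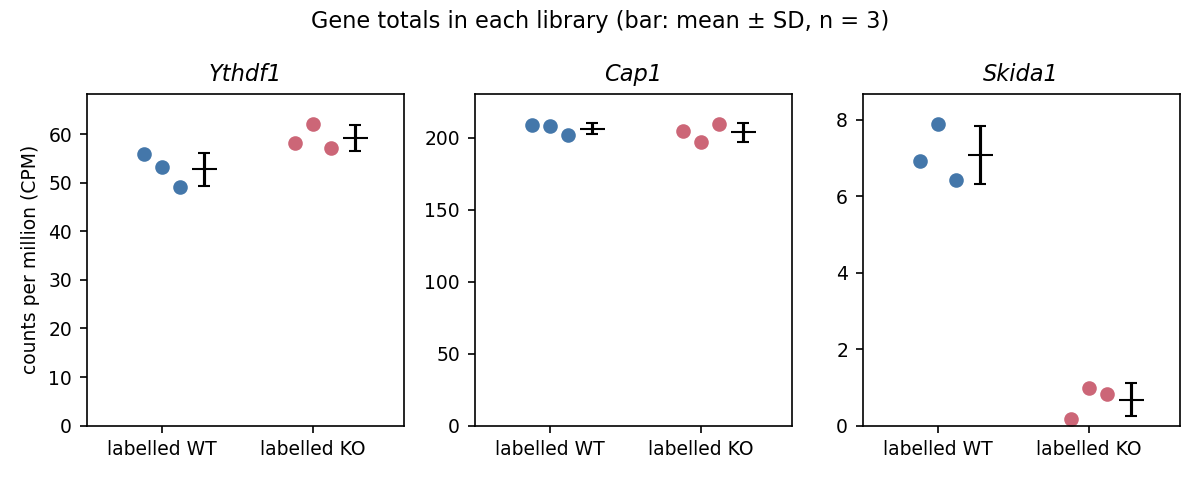
CPM of Ythdf1, Cap1 and Skida1 in each of the 6 libraries, with each group's mean ± SD (n = 3) as a bar. Ythdf1 lay between 57.2 and 62.1 CPM in the libraries labelled KO and between 49.0 and 55.8 CPM in those labelled WT, Cap1 overlapped between groups, and Skida1 lay at 0.99 CPM or less in the libraries labelled KO.

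Among protein-coding genes with the smallest unadjusted p, the clearest difference was in Skida1, which encodes a protein with a SKI/DACH domain. Skida1 (ENSMUSG00000054074, chromosome 2, 18040676 to 18049051) was at 7.08 ± 0.754 CPM in the libraries labelled WT and 0.67 ± 0.430 CPM in those labelled KO (SD, n = 3 each). Its log2 fold change was -3.41 with an SE of 0.45, and the edgeR adjusted p was 0.609. It passed under DESeq2 (adjusted p = 3.24e-15) and, without KO replicate 1, under edgeR (adjusted p = 0.00293), while its adjusted p over all 16 alternatives ran from 3.24e-15 to 0.999. Acta2, the smooth muscle actin, was at 13.8 ± 5.31 CPM in the libraries labelled WT and 6.34 ± 0.152 CPM in those labelled KO. Slc13a3, a dicarboxylate transporter, was at 12.3 ± 1.89 and 7.62 ± 0.249 CPM. Itih2, which encodes a heavy chain of inter-alpha-trypsin inhibitor, was at 5.21 ± 2.51 and 1.96 ± 0.0544 CPM, and Ogn, the small proteoglycan osteoglycin, was at 10.3 ± 4.27 and 4.36 ± 0.868 CPM. Tmem267 was at 32.3 ± 5.30 and 20.1 ± 2.51 CPM. Kitl, the ligand of the Kit receptor, was at 57.4 ± 1.47 and 47.5 ± 1.05 CPM, and Slc38a3, a glutamine transporter, at 76.8 ± 1.54 and 63.9 ± 2.86 CPM. Timp3, an inhibitor of metalloproteinases, had a log2 fold change of -0.33 and Atg9a, an autophagy membrane protein, one of -0.20.

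In the other direction, Rps18, a protein of the small ribosomal subunit on chromosome 17 (33951999 to 33956001), was at 18.1 ± 4.65 CPM in the libraries labelled WT and 44.0 ± 8.06 CPM in those labelled KO (SD, n = 3 each). Its log2 fold change was 1.28 with an SE of 0.19 (edgeR adjusted p = 0.642). Near-identical copies of Rps18 can take its reads, and the copy Gm10260 was at 15.9, 11.4 and 18.2 CPM in WT replicates 1, 2 and 3 and at 1.18, 0 and 0 CPM in KO replicates 1, 2 and 3. H2-D1, a class I histocompatibility gene with a near-identical copy in H2-Q7, was at 14.8 ± 5.21 and 31.7 ± 6.23 CPM. The nuclear noncoding RNA Malat1 was at 551.4 ± 90.3 and 961.7 ± 218.3 CPM. Cpne1, a calcium-dependent membrane-binding protein whose exons overlap those of Rbm12, was at 23.0 ± 2.29 and 34.8 ± 4.98 CPM. Tmsb10, a thymosin that binds actin monomers, was at 59.6 ± 0.252 and 73.2 ± 3.70 CPM. Basp1, a membrane protein of growth cones, had a log2 fold change of 0.21, Tspyl1 one of 0.20 and Mrnip, a DNA repair factor, one of 0.72. The ribosomal protein gene Rplp1 had a log2 fold change of 0.28. The edgeR adjusted p of these genes, higher and lower, lay between 0.609 and 0.881, so none passed the threshold with edgeR.

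Across 20587 tested genes, edgeR's quasi-likelihood test called 0 genes higher and 0 lower at an adjusted p under 0.05, with 1083 genes at an unadjusted p under 0.05 (5.26%; 1029 would be met by chance). Of those 1083 genes, 540 were higher and 543 lower in the libraries labelled KO; with upper-quartile factors the split was 485 and 601, and with library totals alone 598 and 489. limma voom called 0 genes (1156 at an unadjusted p under 0.05), and DESeq2 called 8 higher and 23 lower (1190 at an unadjusted p under 0.05), among them Skida1, Rps18, Cpne1, Acta2, Ogn and Tmem267. Leaving out 1 library called Gm29253 higher (without WT replicate 2, log2 4.25), Rps13 higher and ENSMUSG00000117098 lower (without WT replicate 3, log2 1.63 and -7.87), Gm10260 and Skida1 lower (without KO replicate 1, log2 -12.9 and -2.95), and Gm13443 and AC165951.1 lower (without KO replicate 3, log2 -4.37 and -8.17). These genes other than Skida1 were named after their values were seen. In counts simulated for this comparison over 20034 tested genes, 50 genes with a mean of at least 1 CPM were changed at each fold size. The edgeR test found 8% of those changed 1.2-fold, 48% at 1.5-fold, 70% at 2-fold and 100% at 4-fold. Most shifts of the size seen for Ythdf1 (1.12-fold) would thus have been missed. The simulated spread was more even than the real one (prior degrees of freedom 12.6 against 5.23), so these shares may be too high. Over all 6 libraries Skida1 did not pass with edgeR at a log2 fold change of -3.41, so 0 calls do not exclude large changes.

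The gene lists fixed for the m6A machinery and for actin did not pass the set test over all 6 libraries. The 23 measured writers, erasers and readers of m6A other than Ythdf1 split into 13 higher and 10 lower, with a median log2 fold change of 0.02 (camera adjusted p = 0.478) that was -0.01 without WT replicate 2. The 44 genes of actin turnover split into 24 higher and 20 lower, with a median of 0.01 (camera adjusted p = 0.56). Tmsb10 was the 1 actin turnover gene past the threshold when p was adjusted over the list alone. Over all genes edgeR passed 0 of the list (1 at an unadjusted p under 0.05) and DESeq2 passed Tmsb10 (adjusted p = 0.0283). The Arp2/3 complex and its activators (20 genes, 12 higher) had a median of 0.02 and a camera adjusted p of 0.478, with 0 past the threshold over all genes with edgeR (1 at an unadjusted p under 0.05) or DESeq2 and 0 adjusted over the list alone. Without KO replicate 1 this list passed as higher (median 0.04, camera adjusted p = 0.0327), and its median was below 0 without WT replicate 2 (-0.02) and without KO replicate 3 (-0.01). The 31 measured genes flanking Ythdf1 had a median of 0.03 (camera adjusted p = 0.542), with 0 past the threshold over all genes with edgeR (2 at an unadjusted p under 0.05) or DESeq2 and 0 adjusted over the list alone. Their median was 0.002 without KO replicate 2 and 0.06 without KO replicate 1.

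Ribosomal protein genes were the most uniform group on the higher side. Of 63 measured, 61 were higher in the libraries labelled KO, with a median log2 fold change of 0.18 (95% bootstrap interval over genes 0.16 to 0.21; camera adjusted p = 2.05e-29, and adjusted p = 0.471 with an estimated correlation). Adjusted over the list alone, 25 passed. Over all genes edgeR passed 0 (34 at an unadjusted p under 0.05), and Rps13 without WT replicate 3 (log2 1.63), while DESeq2 passed Rps18 (adjusted p = 0.0048). Some copies of Rps13 and of Rps18 had counts that went the other way, so reads of these genes may have been shared. Rpl30, of the large subunit, was at 23.0 ± 1.82 CPM in the libraries labelled WT and 30.1 ± 2.76 CPM in those labelled KO. The genes of oxidative phosphorylation encoded in the nucleus moved in the same direction, 69 of 73 higher with a median of 0.12 (camera adjusted p = 1.48e-15, and adjusted p = 0.471 with an estimated correlation). Adjusted over the list alone, 0 of these passed, as over all genes with edgeR (15 at an unadjusted p under 0.05) and DESeq2. Uqcrq and Uqcrh of complex III had log2 fold changes of 0.26 and 0.28, and Ndufc2 and Ndufs5 of complex I 0.22 and 0.30. The genes encoded in the mitochondrial genome went the other way: 12 of 13 were lower, with a median of -0.13 (camera adjusted p = 1.23e-12, and adjusted p = 0.471 with an estimated correlation). Of the 13, 8 passed adjusted over the list alone and 0 over all genes with edgeR (10 at an unadjusted p under 0.05) or DESeq2. The complex I subunit mt-Nd5 was at 7736 ± 138.5 CPM in the libraries labelled WT and 6776 ± 396.8 CPM in those labelled KO, and mt-Nd4, mt-Nd4l and mt-Co1 had log2 fold changes of -0.17, -0.15 and -0.14. Mitochondrial genes took 9.40% to 9.95% of the counts in the libraries labelled WT and 8.62% to 9.19% in those labelled KO.

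Mature oligodendrocyte genes were higher in 27 of 28 cases, with a median of 0.30 (camera adjusted p = 1.83e-12, and adjusted p = 0.471 with an estimated correlation). Adjusted over the list alone 0 passed. Over all genes edgeR passed 0 (12 at an unadjusted p under 0.05) and DESeq2 passed Ermn (adjusted p = 0.0355). The myelin gene Mobp was at 711.6 ± 69.6 CPM in the libraries labelled WT and 987.4 ± 265 CPM in those labelled KO, of which KO replicate 1 had 1282 CPM. Ermn, a cytoskeletal protein of myelinating cells, Aspa, which breaks down N-acetylaspartate, and Gjb1, a gap junction protein, had log2 fold changes of 0.46, 0.46 and 0.72. Without KO replicate 1 the list's median was 0.11. Oligodendrocyte precursor genes had a median of 0.06 (camera adjusted p = 0.285), with 0 of 19 past the threshold over all genes with edgeR (1 at an unadjusted p under 0.05) or DESeq2, or adjusted over the list alone. Without KO replicate 1 the precursor median was -0.03, and without KO replicate 3 it was 0.12 and the list passed (camera adjusted p = 0.003).

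Meningeal and leptomeningeal genes were lower in 23 of 23 cases, the largest median shift of the 33 lists, with a median of -0.87 (95% bootstrap interval -1 to -0.61; camera adjusted p = 2.89e-21, and adjusted p = 0.471 with an estimated correlation). Adjusted over the list alone 17 passed. Over all genes edgeR passed 0 (19 at an unadjusted p under 0.05) and DESeq2 passed 6: Ogn, Aldh1a2, Slc13a3, Col1a2, Igfbp2 and Col1a1 (adjusted p = 0.00386 to 0.0437), of which Col1a2, Igfbp2 and Col1a1 were named after their values were seen. Aldh1a2, which makes retinoic acid, was at 8.48 ± 3.57 CPM in the libraries labelled WT and 3.50 ± 0.631 CPM in those labelled KO, and the growth factor gene Igf2 was at 45.4 ± 19.7 and 21.1 ± 3.23 CPM. Relative to the mean of the 6 libraries, the list stood at 0.92, -0.06 and 0.43 (log2) in WT replicates 1, 2 and 3 and at -0.35, -0.76 and -0.18 in KO replicates 1, 2 and 3, and its median was -0.56 without WT replicate 1. Vascular markers moved with it. Endothelial genes were lower in 21 of 23 cases, with a median of -0.33 (camera adjusted p = 2.63e-11, and adjusted p = 0.471 with an estimated correlation), and 0 passed adjusted over the list alone. Over all genes edgeR passed 0 of these (11 at an unadjusted p under 0.05) and DESeq2 passed Itm2a (adjusted p = 0.024). Itm2a, the angiopoietin receptor Tek, the phosphatase gene Ptprb and the VEGF receptor Kdr had log2 fold changes of -0.59, -0.48, -0.40 and -0.48. The endothelial median was -0.21 without KO replicate 1. Pericyte and smooth muscle genes were lower in 16 of 17 cases, with a median of -0.26 (camera adjusted p = 2.42e-08, and adjusted p = 0.471 with an estimated correlation). Of these, Acta2 alone passed adjusted over the list alone; over all genes edgeR passed 0 (9 at an unadjusted p under 0.05) and DESeq2 passed Acta2 (adjusted p = 0.00183). Anpep, Myl9 and Rgs5 had log2 fold changes of -0.73, -0.38 and -0.30.

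**Figure D2:**
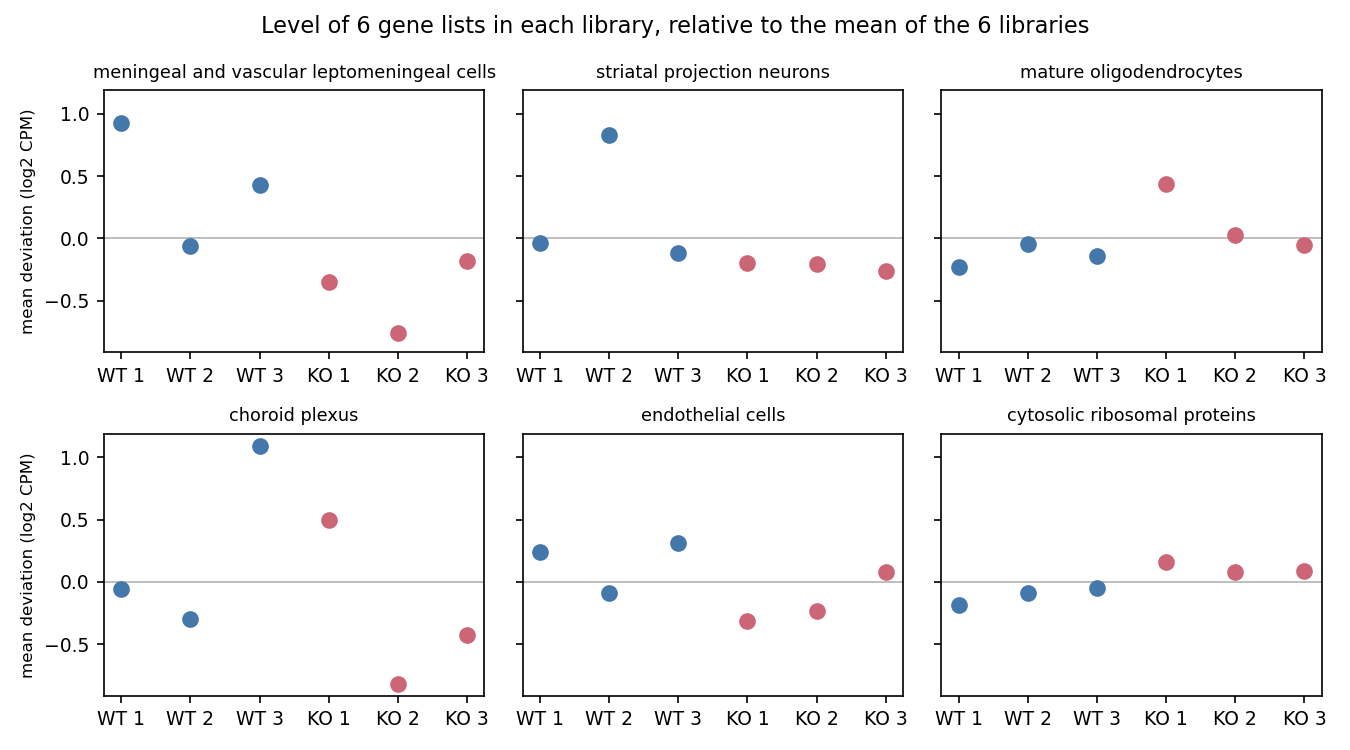
Mean deviation of the members of 6 gene lists from their mean over the 6 libraries, in log2 CPM, with 1 point per library. WT replicate 2 stood at 0.83 for striatal genes, KO replicate 1 at 0.44 for oligodendrocyte genes and WT replicate 3 at 1.09 for choroid plexus genes.

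Striatal projection neuron genes were lower in 21 of 22 cases, with a median of -0.40 (camera adjusted p = 7.17e-07, and adjusted p = 0.471 with an estimated correlation). Penk, Actn2 and Pde10a passed adjusted over the list alone. Over all genes edgeR passed 0 (6 at an unadjusted p under 0.05) and DESeq2 passed Penk (adjusted p = 0.0283). The phosphodiesterase gene Pde10a was at 115.8 CPM in WT replicate 2, against 74.8 and 58.2 CPM in WT replicates 1 and 3 and 48.1 to 49.5 CPM in the libraries labelled KO. The enkephalin precursor gene Penk had a log2 fold change of -0.58, the actin crosslinker gene Actn2 -0.34 and Sh3rf2 -1.95. Sh3rf2 was at 3.06 CPM in WT replicate 2 and at 0.13 to 0.72 CPM in the other libraries. With 1 library left out its log2 fold change ran from -2.6 to -0.656. Without WT replicate 2 the list's median was -0.04 and its camera adjusted p was 0.0358. Choroid plexus genes were lower in 16 of 17 cases, with a median of -0.47 (camera adjusted p = 0.0103, and adjusted p = 0.769 with an estimated correlation), and 0 passed over all genes with edgeR (0 at an unadjusted p under 0.05) or DESeq2, or adjusted over the list alone. Msx1, Enpp2, F5 and Kcnj13 had log2 fold changes of -0.60, -0.14, -0.97 and -0.66. Counts of Msx1, F5 and Kcnj13 were low, with means of 1.69, 1.27 and 0.90 CPM in the libraries labelled WT. In those labelled KO the means were 1.12, 0.65 and 0.57 CPM. Enpp2 also stands in the mature oligodendrocyte list. That call was lost without WT replicate 3 (median 0.07, camera adjusted p = 0.472), without KO replicate 2 (median -0.13, adjusted p = 0.285) and without KO replicate 3 (median -0.58, adjusted p = 0.0666).

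Among the neurons of the cortex itself, upper-layer excitatory genes were lower in 12 of 14 cases, with a median of -0.11 (camera adjusted p = 0.00302, and adjusted p = 0.471 with an estimated correlation). The transcription factor gene Cux2 was at 52.6 CPM in KO replicate 1 and at 77.8 to 103.9 CPM in the other libraries, and the calcium-binding protein gene Calb1 at 71.9 CPM in KO replicate 1. Stard8 and Rasgrf2 had log2 fold changes of -0.27 and -0.14. The upper-layer call was lost without KO replicate 1 (median -0.08, camera adjusted p = 0.341) and without WT replicate 1 (median -0.06, adjusted p = 0.0724), and the median was -0.17 without WT replicate 2 and -0.19 without KO replicate 2. Deep-layer excitatory genes were higher in 15 of 23 cases, with a median of 0.09 (camera adjusted p = 0.0284, and adjusted p = 0.471 with an estimated correlation). Fezf2, which specifies subcerebral projection neurons, was at 41.8 ± 2.18 CPM in the libraries labelled WT and 49.2 ± 1.67 CPM in those labelled KO, and Hs3st4, Rprm and Crym had log2 fold changes of 0.34, 0.37 and 0.18. The deep-layer call was lost without WT replicate 1 (median 0.01, camera adjusted p = 0.35) and without KO replicate 1 (median 0.07, adjusted p = 0.114). In each of these lists 0 genes passed over all genes with edgeR (1 upper-layer and 3 deep-layer genes at an unadjusted p under 0.05) or DESeq2, or adjusted over the list alone.

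Excitatory postsynaptic genes were lower in 29 of 42 cases, by a median of -0.05 (camera adjusted p = 0.0197, and adjusted p = 0.869 with an estimated correlation). The kainate receptor gene Grik5 and the scaffold genes Shank3 and Baiap2 had log2 fold changes of -0.18, -0.12 and -0.13. With 1 library left out these ran from -0.227 to -0.0998, -0.147 to -0.0762 and -0.206 to -0.0288. The direction turned without KO replicate 1 (median 0.01, camera adjusted p = 0.519), and the call was lost without WT replicate 1 (median -0.03, adjusted p = 0.166). Receptors for monoamines and neuropeptides were lower in 23 of 33 cases, with a median of -0.11 (camera adjusted p = 0.0372, and adjusted p = 0.664 with an estimated correlation). Drd1 and Drd2 of this list also stand in the striatal list, and Htr3a in the interneuron list. The dopamine receptor gene Drd2 was at 7.07 CPM in WT replicate 2 and at 0.43 to 1.62 CPM in the other libraries, and Npy1r, Htr5a and Adra1d had log2 fold changes of -0.24, -0.20 and -0.16. The receptor call was lost without KO replicate 1 (median -0.06, camera adjusted p = 0.703), without WT replicate 1 (median -0.08, adjusted p = 0.103), without WT replicate 2 (median -0.07, adjusted p = 0.274) and with no filter on low counts (adjusted p = 0.0564), and the median was -0.18 without KO replicate 3. In both lists 0 genes passed over all genes with edgeR (2 postsynaptic and 0 receptor genes at an unadjusted p under 0.05) or DESeq2, or adjusted over the list alone.

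**Figure D3:**
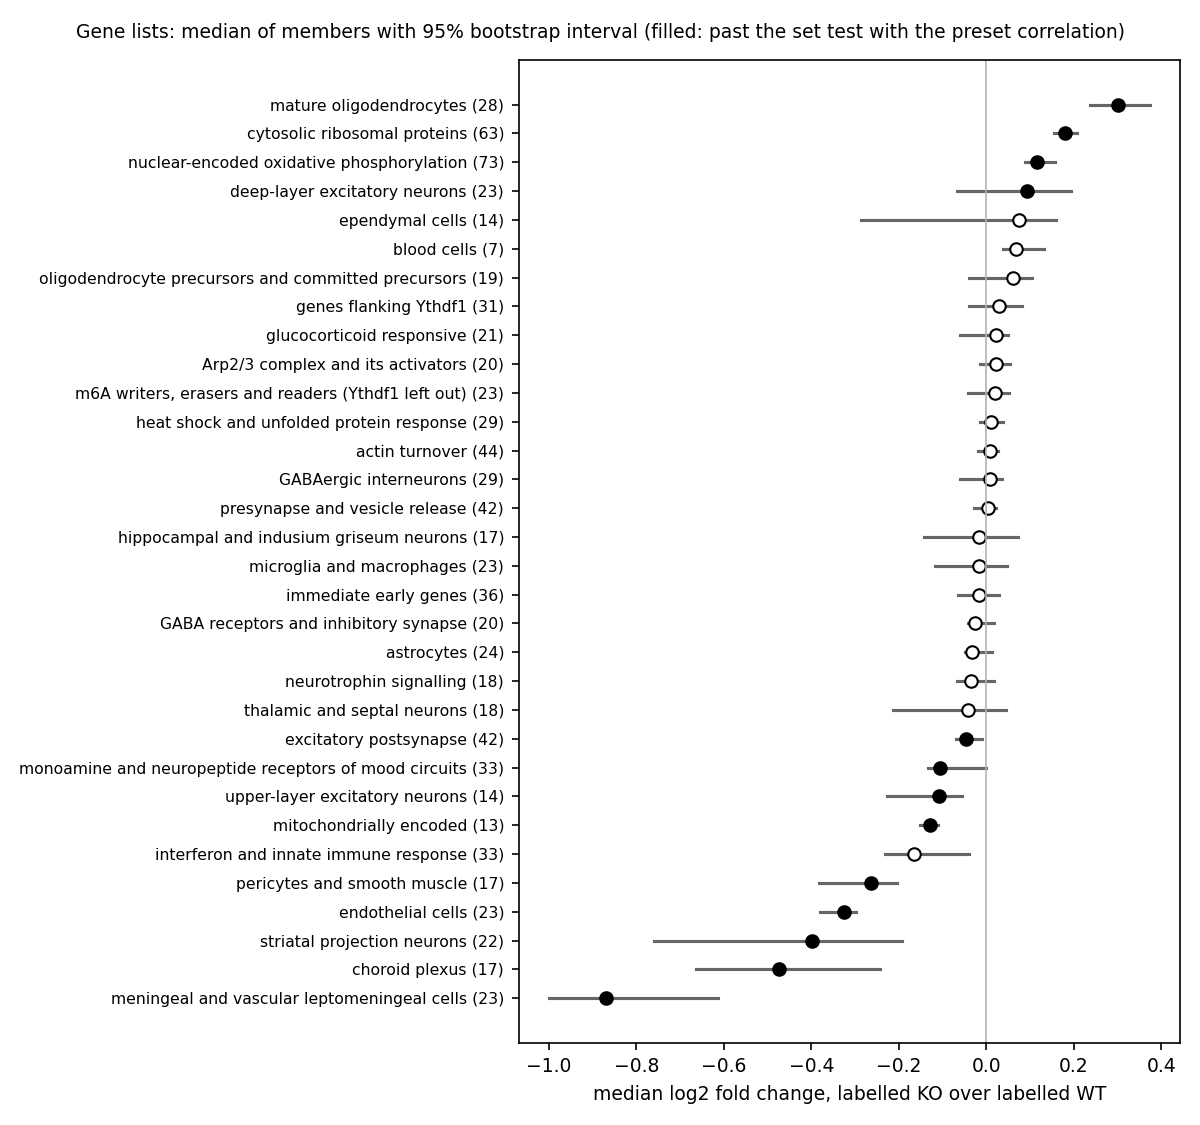
Median log2 fold change of the members of each gene list shown, libraries labelled KO over libraries labelled WT, with the number of measured genes in brackets and the 95% bootstrap interval over genes as a line. Filled points mark the 13 lists past the set test with the preset correlation; with an estimated correlation 0 lists passed.

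The remaining lists did not pass the set test over all 6 libraries. Genes of the presynapse (42 measured) had a median of 0.01 (camera adjusted p = 0.818), GABA receptors and inhibitory synapse genes (20) -0.02 (0.542), and neurotrophin signalling genes (18) -0.04 (0.542). Immediate early genes (36) had a median of -0.02 (camera adjusted p = 0.946), glucocorticoid-responsive genes (21) 0.02 (0.946), and heat shock and unfolded protein response genes (29) 0.01 (0.779). GABAergic interneuron genes (29) had a median of 0.01 (camera adjusted p = 0.778), astrocyte genes (24) -0.03 (0.537), and microglia and macrophage genes (23) -0.02 (0.56). Ependymal genes (14) had a median of 0.07 (camera adjusted p = 0.617), blood cell genes (7) 0.07 (0.246), thalamic and septal genes (18) -0.04 (0.478), and hippocampal and indusium griseum genes (17) -0.02 (0.763). The presynaptic and interneuron medians turned from above to below 0 with upper-quartile factors. Interferon and innate immune genes were lower in 24 of 33 cases, with a median of -0.17 (camera adjusted p = 0.537). Leaving out 1 library made 7 of these lists pass. Interferon genes passed as lower without WT replicate 2 (median -0.26, camera adjusted p = 0.00181) and as higher without WT replicate 3 (0.08, 0.0231). Immediate early genes passed as higher without WT replicate 1 (0.06, 0.00603) and as lower without WT replicate 2 (-0.08, 0.0331). Ependymal genes (0.49, 0.018) and blood cell genes (0.17, 0.0465) passed as higher without WT replicate 2. Lower lists were astrocytes without KO replicate 1 (median -0.10, camera adjusted p = 5.59e-05), microglia without KO replicate 2 (-0.09, 0.0286) and thalamic and septal genes without KO replicate 3 (-0.08, 0.0359). The ependymal median was -0.20 without WT replicate 3, the microglial one 0.07 without KO replicate 3 and the thalamic one 0.04 without KO replicate 2. Over the libraries left out, each of these lists other than blood cells had medians on both sides of 0. Median and mean were above 0 while the test pointed down for the presynaptic, interneuron and glucocorticoid lists. For immediate early genes both were below 0 while the test pointed up. The neurotrophin median and test were below 0 and its mean above, and the hippocampal median was below 0 and its mean and test above. H2-D1, in the interferon list, was the 1 gene of these lists past the threshold adjusted over the list alone, and 0 passed over all genes with edgeR (0 to 6 per list at an unadjusted p under 0.05) or DESeq2.

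The authors' deposited table listed 537 transcripts of 491 genes as differing between genotypes, 250 higher and 287 lower in the libraries labelled KO. In the authors' deposited table the largest q was 0.0496 and the smallest absolute log2 ratio 1.01, and 355 of the transcripts were protein coding, 55 retained an intron and 55 were marked for nonsense-mediated decay. The groups' FPKM values did not overlap for 498 transcripts (92.7%, where 10% is the chance share for groups of 3), and the transcripts were listed because they differed. All 3 libraries of the lower group were listed at 0 for 182 transcripts, and for 12 transcripts over 90% of the higher group's FPKM came from 1 library. The table listed 0 transcripts of Ythdf1 and 0 of Cap1.

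Transcripts entered the table at an absolute log2 ratio of at least 1.01, a selection that the gene totals did not pass through, so the sizes of both cannot be compared directly. For the 354 transcripts with both groups above 0 and a tested gene, the median absolute log2 ratio was 2.40 in the authors' deposited table, and the median absolute log2 fold change of their gene totals was 0.06. The median absolute log2 fold change was 0.07 for all listed genes and 0.11 for all tested genes. Of the 477 listed genes tested on counts, 53 (11.1%) had a gene total at an unadjusted p under 0.05. Of 450 genes listed in 1 direction, 280 (62.2%) had a gene total in that direction. The reads of a listed transcript are part of its gene total and come from the same libraries, so some shared direction follows from the selection, and no share without change was estimated. The formin gene Diaph1, of the actin turnover list, had 1 protein-coding transcript at 0.062, 0.052 and 0.17 FPKM in WT replicates 1, 2 and 3 and at 7.28, 8.42 and 8.14 FPKM in KO replicates 1, 2 and 3 in the authors' deposited table. A second protein-coding Diaph1 transcript went from 9.17, 8.74 and 9.22 FPKM to 0.33, 0.59 and 0.80 FPKM in that table, and the gene total had an edgeR log2 fold change of -0.09. A transcript of the vesicular glutamate transporter gene Slc17a7 with a retained intron was at 47.9 to 64.0 FPKM in the libraries labelled WT and 3.35 to 5.77 FPKM in those labelled KO in the authors' deposited table, with a gene log2 fold change of -0.07. A transcript of the postsynaptic scaffold gene Homer1 was at 17.02 to 26.2 and 5.45 to 6.72 FPKM in the authors' deposited table, and another at 5.16 to 10.9 and 15.4 to 19.5 FPKM, with a gene log2 fold change of -0.07. The clock gene Per1 had a transcript at 8.93 to 10.1 FPKM in the libraries labelled WT that was listed at 0 in all 3 labelled KO in the authors' deposited table, with a gene log2 fold change of -0.04. For Skida1 the transcript and the gene went together: 1.36 to 1.62 FPKM in the libraries labelled WT in the authors' deposited table, and listed at 0 in those labelled KO. These transcripts were singled out after their values were seen, and a value of exactly 0 can be a failed estimate.

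**Figure D4:**
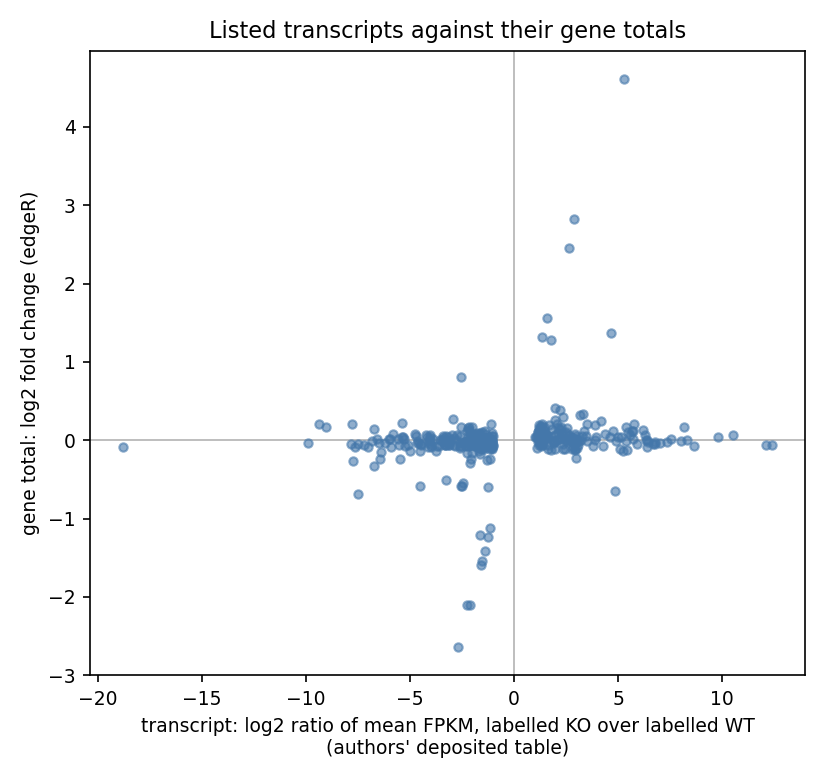
Log2 ratio of mean FPKM of each listed transcript in the authors' deposited table (x axis) against the edgeR log2 fold change of its gene total (y axis), libraries labelled KO over libraries labelled WT, for the 354 transcripts with both groups above 0 and a tested gene. The gene total differed by less than 0.5 on the log2 scale for 329 of them.

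Calls at the adjusted threshold could share nothing with that table, since edgeR called 0 genes. Of the genes at an unadjusted p under 0.05, 19 were higher and also listed higher in the authors' deposited table, against 6.37 by chance (odds ratio 3.23, Fisher's exact p = 2.44e-05). On the lower side 31 genes were shared, against 6.88 by chance (odds ratio 5.21, Fisher's exact p = 2.74e-12). Both lists come from the same 6 libraries, so the overlap is not independent evidence. Members of the fixed lists in the authors' deposited table included Dlg2, Dlgap1, Grik5 and Homer1 of the postsynapse (2 transcripts higher, 7 lower), Igf2 and Ogn of the meningeal list, 7 ribosomal protein genes (3 transcripts higher, 4 lower), Acta2 and Penk.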

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

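Tests with edgeR's robust=TRUE and legacy=FALSE options, upper-quartile factors for the lists and counts thinned to 50% were chosen after the result was seen. edgeR called 0 genes higher and 0 lower with RLE, upper-quartile and library-total scaling, with either other filter on low counts, with robust=TRUE, and with a log2 fold change of at least 1 added to the adjusted p, and limma voom also called 0 (915 to 1359 genes at an unadjusted p under 0.05 over these). DESeq2 called 8 higher and 23 lower, legacy=FALSE called 2 lower (Gm10260 and Skida1), and an unadjusted p under 0.05 with a log2 fold change of at least 1 gave 73 higher and 111 lower. Leaving out 1 library gave 0 to 1 genes higher and 0 to 2 lower. Cap1 ran from -0.041 to 0.0082 over the libraries left out and its one reversal was that without KO replicate 2. Ythdf1 stayed higher in the libraries labelled KO in all 16 alternatives, at 0.12 to 0.21. Of 1085 alternative values of the 68 named genes, 1084 kept their direction and 19 passed the threshold, 17 of them under DESeq2 and 2 for Skida1. Most of these genes were chosen by a small p in the main fit, and the alternatives reuse its libraries. Kept directions follow in part from that choice.

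Camera passed 4 lists higher and 9 lower with the preset correlation. With an estimated correlation it passed 0 and 0, and fry passed 0 and 0. Neither of these was tried on simulated lists, so passing 0 does not show that no list differed. Leaving out 1 library gave 4 to 6 lists higher and 6 to 10 lower, and the excitatory postsynapse reversed without KO replicate 1 (camera adjusted p = 0.519, against 5.74e-05 to 0.519 over the libraries left out). The overlap with the authors' deposited table rose from 0 to 19 higher and 31 lower genes when unadjusted p was used. For each of these changes the cause was not tested, other than that a looser threshold admits more genes. With the replicate number as a replicate block, 0 genes were higher and 0 lower (916 at an unadjusted p under 0.05) and 4 lists higher and 9 lower passed. The numbers gave no clear sign of pairing the libraries. Deviations from the group means correlated across genes at -0.042, 0.040 and 0.026 for replicates 1, 2 and 3, against -0.055 to 0.033 for unlike numbers. Not every library correlated best with its own number, though WT replicate 2 and KO replicate 2 did. Correlations this small cannot exclude that equal numbers shared a batch. With 50% of the reads kept at random, edgeR tested 18708 genes and called 0 higher and 0 lower (1053 at an unadjusted p under 0.05). The lower depth dropped rare genes. Calls were already at 0 with all reads and could not fall, so they do not show how the result depends on depth. In simulated counts of this size 8% of 1.2-fold, 48% of 1.5-fold, 70% of 2-fold and 100% of 4-fold changes were called. The simulated spread was more even than the real one, so these shares may be too high. Other numbers of libraries were not simulated.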

Other observations

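Chosen after the result was seen were both tests on meningeal markers, the test on genes matched to ribosomal protein genes and, for chromosome 17, the tests on linked variants of one genotype, on variants that differ whatever the genotype and on near-identical copies, as were the medians of these tests with 1 library left out; the genes below were also picked after their values were seen. The counts assigned to a ribosomal protein gene and to its pseudogenes differed in opposite directions. Rps13, of the small ribosomal subunit, was at 8.28, 10.4 and 23.2 CPM in WT replicates 1, 2 and 3 and at 31.9, 27.9 and 27.4 CPM in KO replicates 1, 2 and 3. Its processed pseudogene Rps13-ps2 was at 12.3, 12.8 and 5.16 CPM and at 2.68, 4.26 and 3.14 CPM, and Rps13-ps1 at 7.86, 8.44 and 3.29 CPM and at 2.14, 2.66 and 1.95 CPM. In both pseudogenes WT replicate 3 lay closest to the libraries labelled KO, as it did for Rps13.

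Among genes outside the named set that passed under DESeq2, the collagen genes Col1a1 and Col1a2 had edgeR log2 fold changes of -0.87 and -0.80 and the growth factor binding protein gene Igfbp2 one of -0.61, all 3 members of the meningeal list. Ywhag, a 14-3-3 protein, was at 983.4 ± 12.5 CPM in the libraries labelled WT and 1128 ± 36.1 CPM in those labelled KO. Glo1, which detoxifies methylglyoxal, was at 115.8 ± 12.8 and 81.7 ± 14.4 CPM. edgeR's adjusted p was 0.881 for each of these genes.

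Genes on chromosome 17 from 30 to 40 Mb, around the H2 complex, were overrepresented among those at an unadjusted p under 0.01: 11 of 225 genes, the smallest p of 279 windows (exact hypergeometric p = 3.84e-05), with Glo1, Myo1f, Vps52, C4a and A930015D03Rik lower and Pfdn6, Rps18, Atp6v1g2, H2-D1, H2-T24 and H2-T23 higher. Variants carried by one genotype alone, as the account of the whole window, are argued against by 1 other split of the libraries. That split, WT replicates 1 and 3 with KO replicate 3 against the rest, had an exact hypergeometric p of 1.89e-05 in the same window. Like every other split, it exchanges only 1 library of each group, here WT replicate 2 and KO replicate 3. Variants of one genotype at some of the genes therefore stay open. The window ranked first in 2 other splits, so sequence variants that differ among the mice whatever their genotype may account for it, a hypothesis found and tested on the same data. The second of these, WT replicates 1 and 2 with KO replicate 3, had a hypergeometric p of 0.00131 (0.366 adjusted over windows). In the split of WT replicate 1 with KO replicates 2 and 3, a window of chromosome Y at 90 Mb had a hypergeometric p of 5.59e-06. Values this small thus arose in splits other than the genotypes. Reads shared between near-identical copies stay open, since the genes with no stretch of 150 bases at 95% identity in another gene left 4 of 120 in the window (exact hypergeometric p = 0.0286, and 0.107 with 1 gene fewer). An antigen presentation response was expected to put the interferon list outside chromosome 17 above 0.2. Over all 6 libraries its median was -0.137 (bootstrap interval -0.215 to -0.0384), which lay below the bound of 0.1 set beforehand and so went against the response. That interval covers genes and not libraries. Without WT replicate 3, a check added later, the median was 0.09 (-0.01 to 0.28), near that bound. The answer thus depends on 1 library, and the response stays open.

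Meningeal markers were lower in the libraries labelled KO, and within each group their deviations moved together, with a mean pairwise correlation of 0.663 across members while the central 95% of 1000 random lists ended at 0.079. Less meningeal tissue in the dissections labelled KO would give such a pattern, and stays a hypothesis. Random lists are a weak comparison, since markers of 1 cell type can move together whatever parts the groups. The correlation therefore cannot tell this hypothesis from an effect of genotype on meningeal cells. The most abundant members were Ptgds, at 298.3 ± 87.0 and 248.8 ± 69.5 CPM in the libraries labelled WT and KO, and Igf2, and 0 of the 23 genes stood in another list. A lower share of every cell type other than neurons needs all of them lower, and is argued against by the oligodendrocyte median of 0.302, which was 0.11 without KO replicate 1 (bootstrap interval over genes 0.07 to 0.18); the list's level in KO replicate 3 (-0.05) lay below that in WT replicate 2 (-0.04), and the astrocyte and microglia medians were -0.03 and -0.02, so a lower share of those types stays open. An effect of genotype on meningeal cells stays open and was not tested.

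Ribosomal protein genes were higher in the libraries labelled KO by a median of 0.181. After a spline fit on gene length and GC content the median was 0.182 (bootstrap interval 0.136 to 0.201), but the fit held 0.387% of the variance over all genes and so tests little by itself. Length and GC bias as the whole cause is argued against by 1147 genes outside the list, matched to it in length and GC. Their median was 0.0207 (bootstrap interval over genes 0.003 to 0.037). With 1 library left out it was 0.006 to 0.031, against 0.144 to 0.213 for the list. The matched genes were of any gene type and were not matched in expression. A length or GC bias that acts mainly on abundant mRNA therefore stays open. With the counts of 193 named pseudogenes of 46 of the genes added the list's median was 0.183, which argues against shared reads with those pseudogenes as the cause. Copies under other names, such as Gm10260 of Rps18, were not added, so shared reads with them stay open. Differences in RNA handling or cell makeup between the samples, and the genotype itself, stay open and were not tested.

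The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. With edgeR the real split called 0 genes and the highest other 4; 10 of 10 splits called at least 0, as any count must. The real split had 1083 genes at an unadjusted p under 0.05 and the highest other 1408, with 3 of 10 splits as high. The real split passed 13 lists with the preset correlation and the highest other 17, with 6 of 10 splits as high, and with an estimated correlation each of the 10 splits passed 0 lists.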
